A study of Mus musculus with 15 samples.

How the data were processed

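RNA from 15 MC38 tumours was measured by stranded mRNA sequencing, with paired reads of 150 bp. The tumours fell into 4 groups by what was injected into them: vehicle (n = 3), BO-112 (n = 4), DMXAA (n = 4) and BO-112 with DMXAA (n = 4). Per the submitters' processing notes the authors used STAR, the mm39 genome, edgeR and limma. The deposited table used here holds log2 counts scaled to library size (log2 CPM) for 17712 genes in all 15 libraries. Its values lie on the log2 scale with 0.5 reads added before the log, and the library sizes behind them carry a scaling factor for each library. From these values the reads of each gene were recovered as whole numbers, with a largest distance from a whole number of 5.4e-09 against a tolerance of 1e-06, for 100% of the values. The deposited raw count table carries no sample names, so its 15 per-sample columns were not used in any step.

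The recovered reads per library lay between 12725316 and 19660511 and the scaling factors between 0.85 and 1.08. Counting error is therefore small for abundant genes and large for genes near or below 1 CPM, and intervals given are those of the fitted model at a confidence level of 95%. The 17712 genes are those the authors kept, and no further filter was applied before the tests. Gene symbols were attached by Ensembl gene identifier from GENCODE release M21, which gave a symbol to 17636 genes and none to 76. That annotation lies on another build than the one the authors used, so no coordinates are given, and it served only for symbols and transcript lengths. There were 6 symbols shared by more than 1 gene identifier.

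The tests used R 4.3.3 and limma 3.58.1. A linear model with a mean for each of the 4 groups was fitted to the deposited log2 CPM of all 15 libraries, with an intensity trend in the variance and robust empirical Bayes moderation. From it came 6 pairwise comparisons and the interaction, which is the change from BO-112 to both agents less the change from vehicle to DMXAA on the log2 scale. P-values were adjusted by the Benjamini-Hochberg method over all genes within a comparison, with a threshold of 0.05. An edgeR test on raw counts had been chosen in advance but was not run. Limma on the deposited log2 CPM took its place.

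A total of 34 gene lists for pathways and cell types, with 691 distinct symbols of which 628 were measured, were fixed before the data were examined, as were the groups, the comparisons and the alternative analyses, except those named below as added. The 33 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with a correlation estimated from the data. The members past the threshold were counted with p-values adjusted over all genes and with p-values adjusted over the list alone. Means of each list per library were also compared between groups by an exact permutation test.

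Genes named in the text follow a rule fixed in advance. Its first part takes, in each comparison, the 6 genes with the largest positive and the 6 with the largest negative change among those past the threshold, with a mean of at least 1 CPM and with group ranges that do not overlap. Unnamed clones, pseudogenes, mitochondrial genes and receptor segments were left out, and the request on ranges does not apply to the interaction. Its second part takes the 3 members of a list with the smallest adjusted p, and the first member in the other direction where members moved both ways. Its last part is a fixed panel of interferon, cytokine and cell type genes. Not every gene that the rule names is reported here. Levels are given as mean CPM with the SD between tumours, and changes as log2 fold changes with their SE.

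The tests were tried on simulated data with 50 genes shifted at each size. Of genes shifted 4-fold, 84% were found in the comparison of BO-112 with vehicle, 88% for DMXAA, 84% for both agents, and 76% in the interaction. Of genes shifted 2-fold, 56%, 66%, 56% and 26% were found. For both agents against BO-112, both against DMXAA, and BO-112 against DMXAA, 96%, 90% and 96% were found at 4-fold. At 2-fold these were 82%, 60% and 64%. Between 5 and 10 of the unchanged genes were called per comparison. The shifted genes all had a mean log2 CPM above 0. Noise was drawn apart for each gene, so the simulated data held no differences that run through a whole library. The real libraries hold such differences, and 1 split of the DMXAA and vehicle libraries across the treatment called 3899 genes. These shares and false calls therefore need not hold for the real data.

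The alternatives were scaling by ratios to a geometric mean, scaling by total count alone, a stricter filter of at least 1 CPM in at least 4 libraries, limma-voom on the recovered reads, a block for the replicate number, a fit to the 2 compared groups alone, an adjusted p of 0.01 for the overlap, an estimated correlation for the lists, and leaving out each library in turn. After the data were seen, array quality weights, removal of a transcript length trend, leaving out the 4 libraries high in skeletal muscle genes, leaving out libraries of groups not compared, and the permutation test on list means were added. Limma-voom as an alternative for the gene lists was an addition as well. Every comparison was also repeated on other splits of the same libraries.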

Results

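Messenger RNA was sequenced from 15 MC38 tumours, a mouse colon carcinoma line grown under the skin of C57BL/6 mice, 24 h after an injection of 100 µL into the tumour. The tumours measured about 5 mm at treatment. The injected agents were BO-112 (50 µg), a complex of the double-stranded RNA mimic poly I:C with a carrier, and DMXAA (100 µg), an agonist of the mouse DNA-sensing adaptor STING. Vehicle was given to 3 tumours, BO-112 to 4, DMXAA to 4 and both agents to 4. The libraries held 13073772 to 15737746 reads in vehicle tumours, 15677864 to 19070268 with BO-112, 14710769 to 19660511 with DMXAA and 12725316 to 16133547 with both agents. Levels are means of counts scaled to library size (CPM) with the SD between tumours. Changes are log2 fold changes with their SE from limma, adjusted over all measured genes by the Benjamini-Hochberg method.

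The libraries differed within groups. Skeletal muscle genes were high in vehicle 2, BO-112 1, DMXAA 1 and DMXAA 3, where Acta1, the muscle actin, stood at 58.0, 163, 291 and 194 CPM. DMXAA 2 stood apart from the other DMXAA tumours, with a median correlation of 0.933 with its own group against 0.966 to 0.968 for the other 3. Short transcripts were high and long ones low in that library, by a median log2 difference of 0.70 and -0.54 from the mean of the other 14 libraries. In DMXAA 3 these values were 0.34 and -0.31. In the same libraries the oxidative phosphorylation list had a mean log2 CPM of 7.73 and 7.16, with at most 6.78 elsewhere. No sample labels gave a batch. Libraries of the same replicate number were not alike across groups, with a mean correlation of 0.0152 over 21 pairs against -0.0051 over 63 pairs of other numbers. The replicate number is not the number in the source names, which mostly differed between libraries paired this way. This check therefore cannot show whether a batch or a pairing exists.

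**Figure D1:**
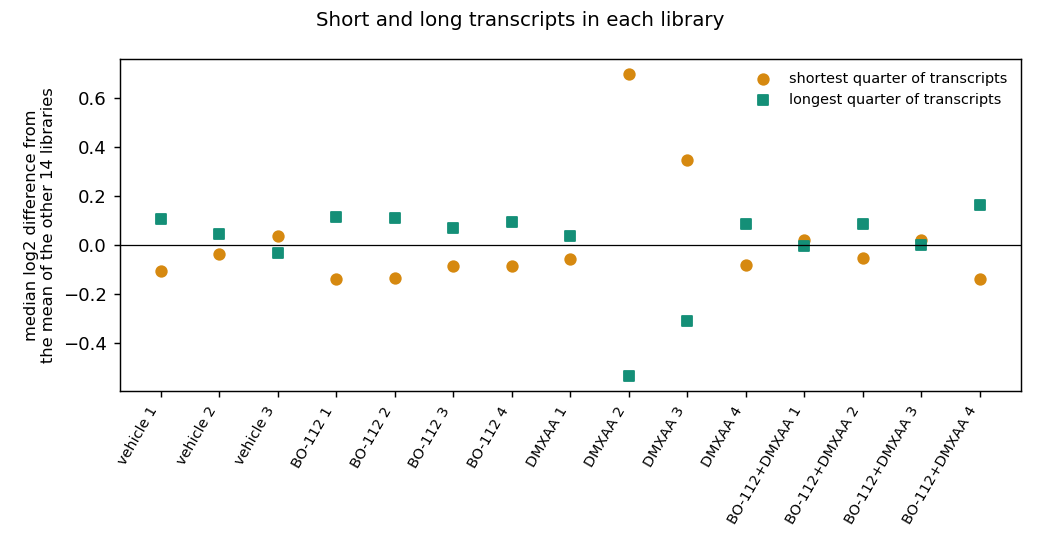
Median log2 difference of each library from the mean of the other 14 libraries, for the shortest and the longest transcripts of the genes measured, with 1 point per library and set. DMXAA 2 lies at 0.70 for short and -0.54 for long transcripts, and DMXAA 3 at 0.34 and -0.31.

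BO-112 against vehicle asks what the RNA mimic changed in the tumour within a day. Interferon beta (Ifnb1, ENSMUSG00000048806.5) went from 0.139 ± 0.0443 CPM (SD, n = 3) to 7.23 ± 2.58 CPM (SD, n = 4), a log2 fold change of 5.70 ± 0.42 with an adjusted p of 1.38e-06. The ubiquitin-like antiviral protein Isg15 (ENSMUSG00000035692.8) rose from 76.8 ± 17.7 to 563 ± 65.2 CPM. Slpi (ENSMUSG00000017002.15), an inhibitor of neutrophil elastase, rose from 0.340 ± 0.169 to 42.7 ± 11.9 CPM. The scavenger receptor Cd163 (ENSMUSG00000008845.10), found on resident macrophages, fell from 4.89 ± 3.67 to 0.184 ± 0.116 CPM. Ciita, the master activator of MHC class II transcription, fell from 53.3 ± 4.42 to 4.34 ± 2.07 CPM.

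All 32 measured type I interferon-stimulated genes rose with BO-112, adjusted over all genes and adjusted over the list alone (median log2 fold change 2.23, limma camera adjusted p = 3.16e-49, adjusted p = 0.0306 with an estimated correlation). Among them were Usp18, which limits interferon signalling (2.98 ± 0.18), Isg15 (2.89 ± 0.20) and Ifit1 (2.67 ± 0.19). The nucleic acid sensing list had 15 of 23 members higher, and 15 higher and 3 lower adjusted over the list alone (camera adjusted p = 3.45e-12, adjusted p = 0.139 with an estimated correlation). Tlr3, the endosomal receptor for double-stranded RNA, rose by 1.45 ± 0.16, while Tmem173, which encodes STING, stood at -0.37 ± 0.15 (adjusted p = 0.13). Inflammatory cytokines and NF-kB targets were higher in 22 of 31, and in 25 adjusted over the list alone (camera adjusted p = 9.58e-22, adjusted p = 0.0306 with an estimated correlation). The interleukin 1 antagonist Il1rn rose by 4.41 ± 0.34, the interleukin 12 subunit Il12b by 3.48 ± 0.36, Il6 by 3.31 ± 0.44 and Tnf by 2.38 ± 0.34. The T cell attractant Ccl5 rose by 4.52 ± 0.36 and Cxcl10 by 2.52 ± 0.37, in a list of lymphocyte and monocyte chemokines with 11 of 19 higher, and 14 higher and 2 lower adjusted over the list alone. That list had a camera adjusted p of 6.66e-09 and an adjusted p = 0.0924 with an estimated correlation.

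MHC class I genes were higher in 12 of 23, and in 17 adjusted over the list alone (camera adjusted p = 2.42e-11, adjusted p = 0.139 with an estimated correlation). H2-T22 rose by 1.42 ± 0.18 and H2-K1 by 0.83 ± 0.16. MHC class II genes were lower in 4 of 13, and in 9 adjusted over the list alone (camera adjusted p = 1.29e-05, adjusted p = 0.345 with an estimated correlation). Besides Ciita, the peptide-loading genes H2-DMb1 (-2.02 ± 0.41) and H2-DMa were lower. Interferon-gamma response genes were higher in 16 of 28 and lower in 1, which was Ciita, and 20 and 2 passed adjusted over the list alone (camera adjusted p = 2.62e-08, adjusted p = 0.345 with an estimated correlation). The median of that list was 1.24, and 0.65 without vehicle 3, whose list mean was 4.57 against 6.10 and 6.58 in the other vehicle tumours. Ifng itself was at 0.16 ± 0.90 (adjusted p = 0.943) and its target Cxcl9 at 1.77 ± 0.56 (adjusted p = 0.0545).

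Markers of neutrophils rose in 10 of 20, and in 12 adjusted over the list alone (camera adjusted p = 3.87e-10, adjusted p = 0.139 with an estimated correlation). Among them were Clec4e (6.37 ± 0.57), the sensor of mycobacterial cord factor, and the iron-binding protein Lcn2 (5.67 ± 0.75). Macrophage markers went both ways, with 7 of 22 lower and 2 higher, and 8 and 3 adjusted over the list alone (camera adjusted p = 0.0852). The mannose receptor Mrc1 was lower (-2.71 ± 0.47) and Gpnmb higher (0.74), while the pan-macrophage marker Adgre1 was at -0.34 ± 0.14 (adjusted p = 0.12). Dendritic cell markers also went both ways, with 5 of 20 lower and 1 higher, and 8 and 3 adjusted over the list alone (camera adjusted p = 0.09). The lectin Mgl2 was lower (-3.87 ± 0.84) and the migration receptor Ccr7 higher (2.11). No T cell marker of 25 passed, over all genes or adjusted over the list alone (camera adjusted p = 0.212), and Cd8a was at 0.02 ± 0.54, with a 95% interval from -1.12 to 1.16. The cytotoxic list had 6 of 18 higher under both adjustments (camera adjusted p = 0.00137, adjusted p = 0.452 with an estimated correlation). Perforin (Prf1, 1.75) and Gzmb (2.41 ± 0.41) were among them. The median of the cytotoxic effector genes was 0.57, with 0.29 without vehicle 3 and 1.00 without vehicle 2. Cell cycle genes were lower in 14 of 28, and in 19 adjusted over the list alone (camera adjusted p = 1.15e-09, adjusted p = 0.259 with an estimated correlation). The mitotic kinases Plk1 (-0.84 ± 0.17) and Aurkb (-0.78 ± 0.16) were lower.

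In total 2116 genes changed with BO-112, 1353 higher and 763 lower, and 750 and 334 of them by at least 2-fold. The count was 1309 without vehicle 1, 1269 without vehicle 3, 3524 without DMXAA 2, 4320 in a fit to these 2 groups alone, 5006 with array quality weights and 1090 without the 4 libraries high in muscle genes, which ended the calls of H2-DMa, H2-DMb1, Aurkb and Gpnmb. With each library left out, 82 of 97 named calls held. Scaling by total count alone put most of the changed genes on the lower side, where 63.9% were higher here.

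**Figure D2:**
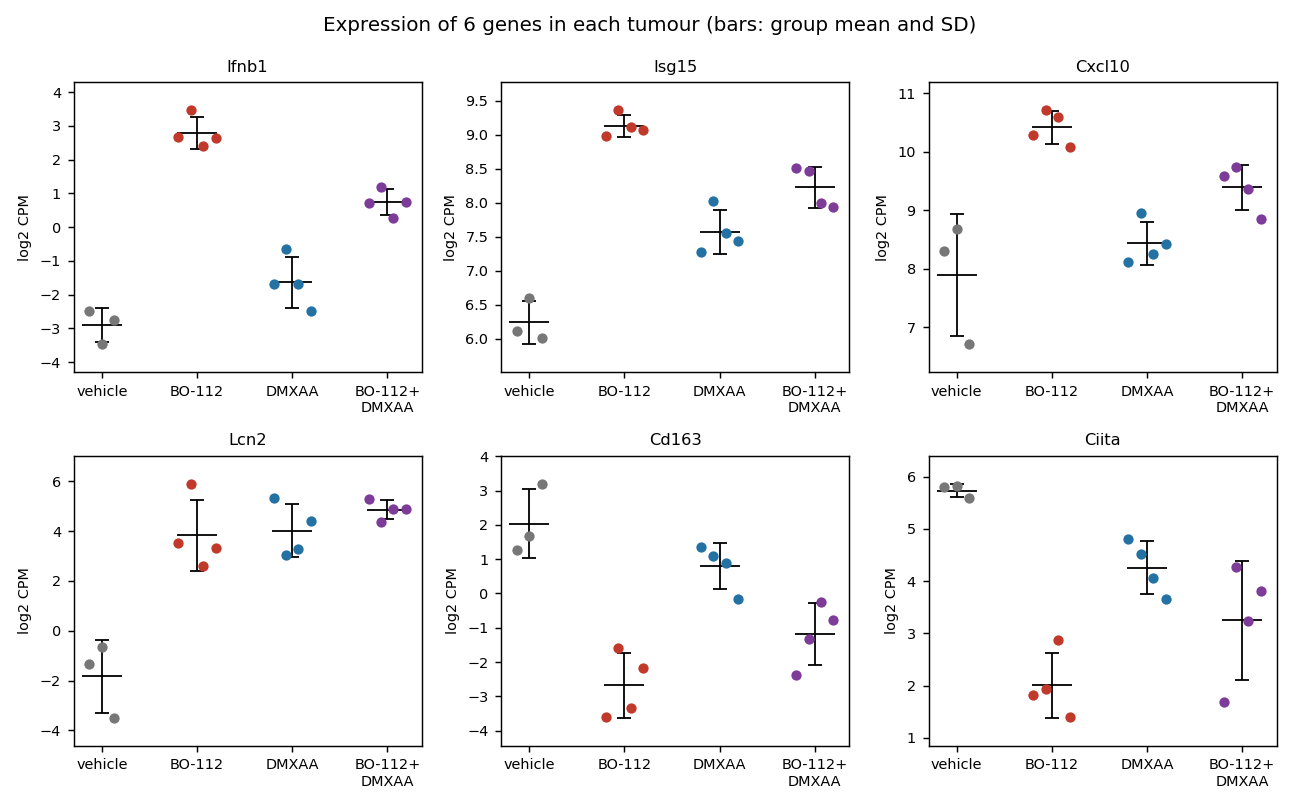
Log2 CPM of 6 genes in each tumour (points), with group mean and SD (bars), for vehicle (n = 3), BO-112, DMXAA and both agents (n = 4 each). Mean Ifnb1 was 0.139, 7.23, 0.360 and 1.71 CPM in that order, and mean Ciita 53.3, 4.34, 20.1 and 11.5 CPM.

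DMXAA against vehicle asks the same of the STING agonist. The iron-binding neutrophil protein Lcn2 (ENSMUSG00000026822.15) rose from 0.372 ± 0.274 CPM (SD, n = 3) to 19.8 ± 14.7 CPM (SD, n = 4), with a log2 fold change of 5.84 ± 0.75 and an adjusted p of 0.00227. The soluble pattern receptor Ptx3 rose by 4.97 ± 0.51 and the neutrophil chemokine Cxcl5 by 4.46 ± 0.65. Among genes that fell were the matrix protein Hmcn1 (-1.69 ± 0.32) and the synaptic vesicle primer Unc13a (-1.09 ± 0.17), both encoded by long transcripts, and their calls ended when the transcript length trend was removed. The end of a call does not by itself show that length set these changes. Ifnb1 stood at 0.360 ± 0.197 CPM, 1.28 ± 0.42 above vehicle with an adjusted p of 0.168.

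With DMXAA 11 of 32 type I interferon-stimulated genes were higher, and 23 adjusted over the list alone, with a positive change in 31 (median 0.78, camera adjusted p = 2.22e-19, adjusted p = 0.369 with an estimated correlation). Rtp4 (1.20 ± 0.15), Ifi27l2a (1.81 ± 0.23) and Oas1a (1.15 ± 0.16), an activator of RNase L, had the smallest p-values of the list, and Isg15 rose by 1.33 ± 0.20. Neutrophil markers rose in 6 of 20 and fell in 1, the gelatinase Mmp9 (-0.92 ± 0.18), and 15 and 1 passed adjusted over the list alone (camera adjusted p = 2.84e-11, adjusted p = 0.369 with an estimated correlation). The alarmin genes S100a9 (4.93 ± 0.79) and S100a8 (4.03 ± 0.81) were among those that rose. Chemokines rose in 7 of 19, and in 8 adjusted over the list alone (camera adjusted p = 3.98e-06, adjusted p = 0.369 with an estimated correlation). They included Ccl4 (2.61 ± 0.40), Ccl7 (2.03 ± 0.32) and the B cell attractant Cxcl13 (3.65 ± 0.68). Monocyte markers rose in 3 of 16, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00714, adjusted p = 0.453 with an estimated correlation). Ly6c2, the marker of inflammatory monocytes, rose by 3.04 ± 0.32. The inflammatory list had 4 of 31 higher, among them Cxcl1 and Cxcl2, and 10 adjusted over the list alone (camera adjusted p = 0.00222, adjusted p = 0.537 with an estimated correlation). Tnf stood at 1.37 ± 0.34 (adjusted p = 0.0678) and Il12b at -0.28 ± 0.36 (adjusted p = 0.662).

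Cytotoxic genes were higher in 2 of 18, and in 9 adjusted over the list alone (camera adjusted p = 2.29e-07, adjusted p = 0.418 with an estimated correlation). The 2 were granzyme A (Gzma, 1.81 ± 0.30) and the granule protein Nkg7 (1.13 ± 0.21). T cell markers had 0 of 25 past the threshold under either adjustment, with 23 positive changes (camera adjusted p = 0.00991, adjusted p = 0.777 with an estimated correlation). Oxidative phosphorylation genes had 0 of 28 past it and a median of 0.35, in a group that held DMXAA 2 and DMXAA 3 (camera adjusted p = 0.000519, adjusted p = 0.738 with an estimated correlation). Adipocyte markers had 0 of 14 past it and a median of 1.53 (camera adjusted p = 0.019, adjusted p = 0.738 with an estimated correlation). MHC class I genes were higher in 2 of 23, H2-T22 (0.97 ± 0.18) and H2-T23 (1.03 ± 0.22), and in 10 adjusted over the list alone (camera adjusted p = 1.59e-07, adjusted p = 0.418 with an estimated correlation). Leaving out DMXAA 1 ended the list calls of T cell, monocyte and adipocyte markers and of the inflammatory list (medians 0.15, 0.40, 1.08 and 0.04), DMXAA 2 those of adipocyte markers and oxidative phosphorylation (0.89 and 0.09), and vehicle 3 that of T cell markers. Without vehicle 3 the medians of cytotoxic effector genes, chemokines and monocyte markers were 0.52, 0.63 and 0.24, from 0.82, 1.24 and 0.53.

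In total 221 genes changed with DMXAA, 191 higher and 30 lower. The count was 25 without vehicle 1, 51 without vehicle 3, 376 without DMXAA 4, 24 without the 4 libraries high in muscle genes, 4 in a fit to these 2 groups alone, 93 with limma-voom, 105 with scaling by total count alone, 147 with the length trend removed and 351 with array quality weights. Of 43 named calls, 10 held with each library left out, those of Lcn2, Ptx3, Cxcl5, Rtp4, Ifi27l2a, Oas1a, Ccl4, Ly6c2, Plac8 and C2. Those fits still take their spread from all groups. In the fit to these 2 groups alone, at most 4 of the 10 calls can hold, since it called 4 genes in all.

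With both agents against vehicle, Lcn2 rose to 29.7 ± 7.46 CPM (SD, n = 4), a log2 fold change of 6.69 ± 0.75 with an adjusted p of 0.000166. The neutrophil chemokines Cxcl2 (5.89 ± 0.91) and Cxcl3 (5.37 ± 0.92) and the alarmin S100a9 (5.75 ± 0.79) rose as well. Ifnb1 rose to 1.71 ± 0.45 CPM (3.64 ± 0.42, adjusted p = 0.000181) and Isg15 to 305 ± 63.2 CPM (1.99 ± 0.20). Cd163 fell to 0.505 ± 0.276 CPM (-3.22 ± 0.62) and Ciita to 11.5 ± 6.87 CPM (-2.48 ± 0.49).

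Type I interferon-stimulated genes were higher in 28 of 32, and in 31 adjusted over the list alone (camera adjusted p = 6.17e-66, adjusted p = 0.0145 with an estimated correlation). Usp18 (2.08 ± 0.18), the inhibitor of viral translation Ifit1 (1.88 ± 0.19) and Oasl1 (3.14 ± 0.29) rose. Neutrophil markers rose in 10 of 20, and 17 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.44e-20, adjusted p = 0.0478 with an estimated correlation). Inflammatory genes were higher in 13 of 31, and in 19 adjusted over the list alone (camera adjusted p = 1.9e-24, adjusted p = 0.0145 with an estimated correlation). Il1rn (3.20 ± 0.34), Il6 (2.72 ± 0.44) and Tnf (2.09 ± 0.34) were among them. The cell death and inflammasome list had 5 of 25 higher, and 8 adjusted over the list alone (camera adjusted p = 1.67e-08, adjusted p = 0.0378 with an estimated correlation). These included the pyroptosis caspase Casp4 (0.94 ± 0.13) and the membrane rupture protein Ninj1 (0.97 ± 0.15). MHC class II genes were lower in 1 of 13, which was Ciita, and in 8 adjusted over the list alone (camera adjusted p = 5.6e-07, adjusted p = 0.281 with an estimated correlation). Cell cycle genes had 0 of 28 past the threshold under either adjustment and a negative change in each of the 28 (median -0.26, camera adjusted p = 3.8e-08, adjusted p = 0.299 with an estimated correlation). T cell markers had 0 of 25 past it (median -0.26, camera adjusted p = 0.00286, adjusted p = 0.59 with an estimated correlation). Gzmb was at 1.34 ± 0.41 (adjusted p = 0.124). Skeletal muscle genes had 0 of 15 past it and a median of -2.35; vehicle 2 was high in them and no library with both agents was (camera adjusted p = 0.000931, adjusted p = 0.543 with an estimated correlation). Leaving out vehicle 2 ended the list calls of skeletal muscle (median -1.15) and T cell markers (-0.06), as did vehicle 1 and replicate 3 with both agents for T cell markers (-0.19 and -0.17), and without replicate 2 with both agents the cell cycle median was -0.17.

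In total 473 genes changed with both agents, 441 higher and 32 lower. The count was 287 without vehicle 1, 246 without vehicle 3, 284 and 300 without replicates 1 and 2 of the tumours with both agents, 768 without DMXAA 2, 748 in a fit to these 2 groups alone and 1403 with array quality weights. Limma-voom ended the calls of Lcn2, Slpi, Cxcl2, Cxcl3, S100a9 and Serpinb2, leaving out vehicle 3 that of Cd163, and the fit without the 4 libraries high in muscle genes that of Ciita. Of 64 named calls, 40 held with each library left out.

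**Figure D3:**
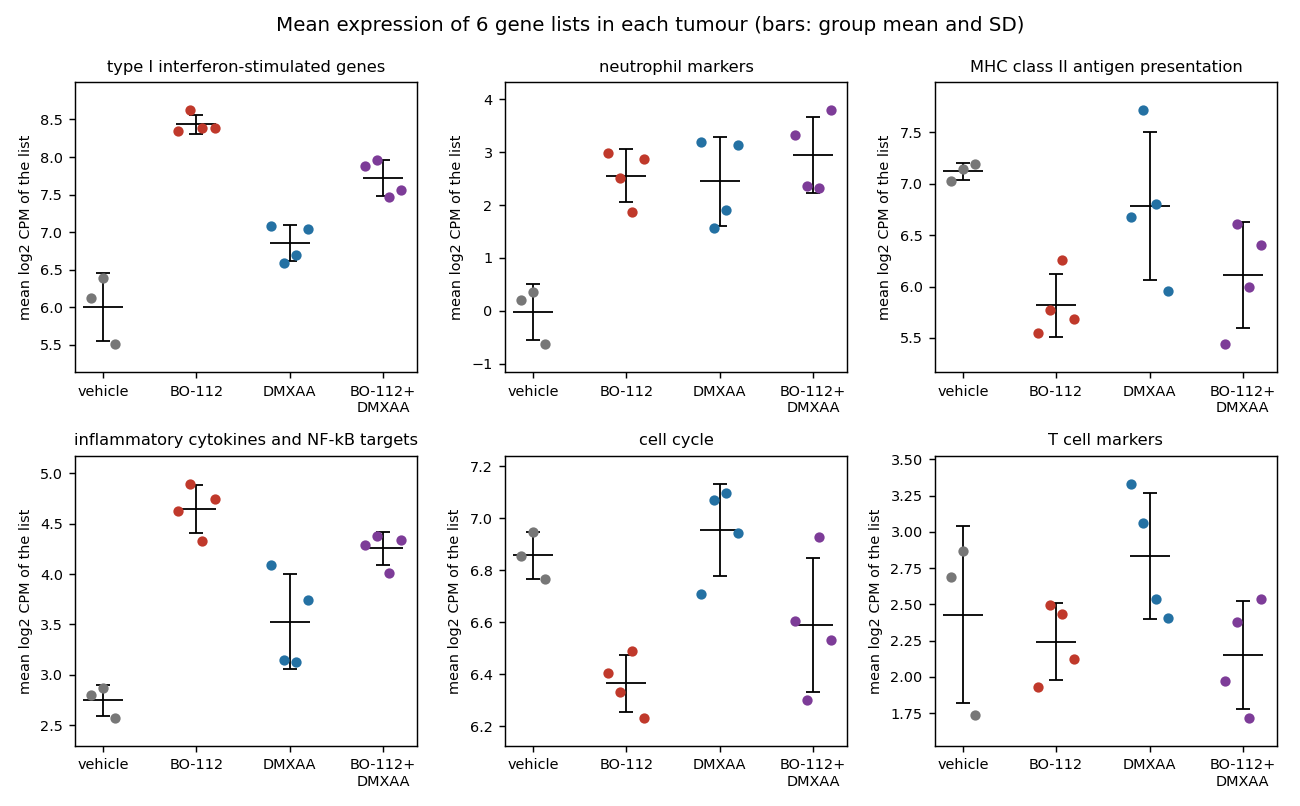
Mean log2 CPM of 6 gene lists in each tumour (points), with group mean and SD (bars), for vehicle (n = 3), BO-112, DMXAA and both agents (n = 4 each). Type I interferon-stimulated genes averaged 6.01, 8.43, 6.85 and 7.72 in that order, and neutrophil markers -0.02, 2.56, 2.45 and 2.95.

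Of the genes called with DMXAA, 165 were also called in the same direction with BO-112, 154 higher and 11 lower, and 0 went in opposite directions. These were 74.7% of the DMXAA calls, where independent lists of the same sizes would share 15.9 genes. Both comparisons used the same 3 vehicle tumours. Simulated unchanged groups, set against 1 simulated vehicle group, shared 0 called genes. Each simulated library, vehicle included, took its deviations from any of the 15 libraries, so the real vehicle tumours were not kept. The simulated count leaves out the effects of the agents and the independent lists leave out the shared tumours, so neither shows a shared effect. Across all genes, which are not independent replicates, the 2 sets of fold changes had a correlation of 0.410. That lay within the 0.0762 to 0.865 that 100 of these simulations gave from a shared simulated vehicle group. The shared calls numbered 21 without vehicle 1, 41 without vehicle 3, 85 with scaling by total count alone, 70 with limma-voom, 107 with the length trend removed, 23 without the 4 libraries high in muscle genes, 289 with array quality weights, 4 with each pair of groups fitted alone and 37 at an adjusted p of 0.01.

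Both agents against BO-112 alone asks what DMXAA added to BO-112. Type I interferon-stimulated genes were lower with both agents in 32 of 32, with a median log2 difference of -0.70, though 0 passed over all genes and 24 were lower adjusted over the list alone (camera adjusted p = 5.19e-32, adjusted p = 0.148 with an estimated correlation). In the same comparison Ifnb1 was at -2.05 ± 0.39 (95% interval -2.88 to -1.23, adjusted p = 0.117) and Isg15 at -0.90 ± 0.18 (adjusted p = 0.139). The mean of the interferon list lay below that of every BO-112 tumour in 4 of 4 tumours with both agents, at 7.72 ± 0.24 against 8.43 ± 0.13 (SD, n = 4 each; exact permutation test, two-sided, p = 0.0286, the smallest it can give, and 0.236 adjusted over 33 lists). Inflammatory genes had 0 of 31 past the threshold over all genes and 14 lower adjusted over the list alone (median -0.47, camera adjusted p = 5.5e-10, adjusted p = 0.148 with an estimated correlation). The nucleic acid sensing list had 0 of 23 past it and 9 lower adjusted over the list alone (camera adjusted p = 1.25e-08, adjusted p = 0.388 with an estimated correlation). Neutrophil markers had 0 of 20 past it under either adjustment, with a median of 0.58 (camera adjusted p = 0.378), and S100a8 was at 1.04 ± 0.75 (adjusted p = 0.741). Cell cycle genes had 0 of 28 past it under either adjustment and 26 positive changes (median 0.24, camera adjusted p = 3.82e-06, adjusted p = 0.53 with an estimated correlation). Skeletal muscle genes had a median of -1.51, with BO-112 1 the library of this pair of groups that was high in them (camera adjusted p = 0.0156, adjusted p = 0.728 with an estimated correlation). The skeletal muscle call ended without BO-112 1 (0.16) or replicate 2 with both agents (-1.50), and without replicate 3 with both agents the cell cycle median was 0.13.

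No single gene passed in that comparison: limma called 0 genes, with 1690 at an unadjusted p below 0.05 and a smallest adjusted p of 0.0839, and limma-voom called 0. The count was 362 in a fit to these 2 groups alone (51 higher, 311 lower), 313 with array quality weights (111 higher, 202 lower), 32 without DMXAA 2, 6 with the length trend removed, 3 with scaling by total count alone and 1 without replicate 1 of the tumours with both agents. The main fit takes its spread from all 15 libraries, so libraries outside these 2 groups enter its count of 0.

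Both agents against DMXAA alone asks what BO-112 added to DMXAA. Il12b rose from 2.86 ± 1.04 to 15.9 ± 3.43 CPM (SD, n = 4 each), a log2 fold change of 2.51 ± 0.33 with an adjusted p of 0.00869. Ifnb1 rose by 2.36 ± 0.39, the serine protease Htra4 by 2.71 ± 0.36 and Acod1, which makes itaconate in activated macrophages, by 2.72 ± 0.43. The macrophage survival factor Cd5l (-3.04 ± 0.50), the lectin Cd209f (-3.68 ± 0.67) and the secreted ribonuclease Rnase6 were lower.

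Of the type I interferon-stimulated genes 14 of 32 were higher, and 27 were higher and 1 lower adjusted over the list alone (camera adjusted p = 2.33e-18, adjusted p = 0.615 with an estimated correlation). Oasl1 (1.89 ± 0.27) and Ifit1 (1.20 ± 0.17) were among those that rose. Inflammatory genes were higher in 7 of 31, and in 17 adjusted over the list alone, with the NF-kB inhibitor Tnfaip3 (1.33 ± 0.20) among them (camera adjusted p = 1.57e-09, adjusted p = 0.502 with an estimated correlation). T cell markers had 0 of 25 past the threshold over all genes and 9 lower adjusted over the list alone (median -0.75, camera adjusted p = 6.42e-07, adjusted p = 0.66 with an estimated correlation). NK cell markers had 1 of 18 lower, Cd244a (-0.83 ± 0.17), and 4 adjusted over the list alone (camera adjusted p = 1.33e-05, adjusted p = 0.66 with an estimated correlation). Moving with these groups, skeletal muscle genes had a median of -3.80 (camera adjusted p = 0.000257, adjusted p = 0.748 with an estimated correlation), adipocyte markers of -1.37 (0.0258, adjusted p = 0.84 with an estimated correlation) and oxidative phosphorylation genes of -0.53 (3.21e-08, adjusted p = 0.66 with an estimated correlation), each with 0 members past the threshold. Without DMXAA 1 the calls of skeletal muscle and adipocyte markers ended (-2.45 and -1.14), as did that of adipocyte markers without DMXAA 2 (-0.69) or replicate 4 with both agents (-0.64), and without DMXAA 2 the medians of NK cell markers and oxidative phosphorylation were -0.45 and -0.20.

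In total 157 genes changed, 127 higher and 30 lower, and none of the 28 named calls held with each library left out. The count was 0 without replicate 1 or without replicate 2 of the tumours with both agents, 47 without replicate 4, 1765, 5 and 1504 without DMXAA 1, DMXAA 3 and DMXAA 4, 71, 90, 75 and 85 without BO-112 1 to 4, 96 without vehicle 1, 272 with the length trend removed, 1 without the 4 libraries high in muscle genes and 4 in a fit to these 2 groups alone.

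BO-112 against DMXAA sets the single agents side by side. Ifnb1 was higher with BO-112 by 4.42 ± 0.39 (adjusted p = 2.87e-05, n = 4 each in limma), Clec4e by 4.38 ± 0.52, Il12b by 3.76 ± 0.33 and the cytokine Tnfsf15 by 3.73 ± 0.43. Lower with BO-112 were Cd209f (-4.47 ± 0.67), Cd163 (-3.46 ± 0.58) and the lectin Clec10a (-3.36 ± 0.71), found on macrophages and dendritic cells, and Rnase6 (-2.89 ± 0.32). Cd274, which encodes the checkpoint ligand PD-L1, stood at 299 ± 11.3 CPM with BO-112 and 84.4 ± 46.0 CPM with DMXAA (2.01 ± 0.35, adjusted p = 0.00178).

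Type I interferon-stimulated genes were higher with BO-112 in 29 of 32 under both adjustments, the second adjusted over the list alone, with Ifit1 (1.99 ± 0.17) and Cmpk2 (2.66 ± 0.24) among them (camera adjusted p = 5.18e-26, adjusted p = 0.274 with an estimated correlation). Inflammatory genes were higher in 20 of 31, and 21 higher and 2 lower adjusted over the list alone (camera adjusted p = 9.03e-12, adjusted p = 0.274 with an estimated correlation). MHC class II genes were lower in 6 of 13 under both adjustments, the second adjusted over the list alone (camera adjusted p = 0.000428, adjusted p = 0.662 with an estimated correlation). Ciita (-2.25 ± 0.45) and the protease Lgmn (-0.72 ± 0.13) were among them. Cell cycle genes were lower in 21 of 28, also adjusted over the list alone (camera adjusted p = 1.21e-09, adjusted p = 0.524 with an estimated correlation), among them Plk1 (-0.93 ± 0.16) and the ribonucleotide reductase subunit Rrm2 (-0.92 ± 0.16). T cell markers were lower in 7 of 25, and in 9 adjusted over the list alone (camera adjusted p = 0.00194, adjusted p = 0.662 with an estimated correlation). The receptor chain gene Trbc2 (-1.27 ± 0.30) and the adaptor Lat (-1.27 ± 0.32) were lower. Skeletal muscle markers had a median of -2.19 with 0 of 15 genes past the threshold (camera adjusted p = 0.143), and adipocyte markers -1.99 with 0 of 14 (camera adjusted p = 0.0657). Neutrophil markers were higher in 4 of 20 under both adjustments, the second adjusted over the list alone, with a median of -0.12 (camera adjusted p = 0.464). Oxidative phosphorylation genes were lower in 10 of 28, and in 17 adjusted over the list alone, with DMXAA 2 and DMXAA 3 the libraries highest in them (camera adjusted p = 3.43e-06, adjusted p = 0.662 with an estimated correlation). Without DMXAA 2 the medians of oxidative phosphorylation and MHC class II genes were -0.28 and -0.40, from -0.60 and -0.74, and leaving out DMXAA 1 ended the T cell list call (-0.54).

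In total 3783 genes differed, 1976 higher and 1807 lower with BO-112, and scaling by total count alone put 35.4% on the higher side against 52.2% here. The count was 2130, 2289 and 2292 without BO-112 1, BO-112 2 and BO-112 4, 5898, 1879 and 5743 without DMXAA 1, DMXAA 3 and DMXAA 4, 1262 in a fit to these 2 groups alone and 791 without the 4 libraries high in muscle genes, which ended the calls of Cd163, Clec10a, Ciita, Trbc2 and Lat. With each library left out, 73 of 97 named calls held.

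The interaction asks whether the change with both agents equals the sum of the log2 changes with each. A sum of log2 changes is a product of fold changes, so a gene can lie below it although its changes in CPM add up. Ptx3 (-5.49 ± 0.70, adjusted p = 0.00249), Slpi (-5.86 ± 1.05), the chemoattractant Rarres2 (-3.97 ± 0.60) and Ly6c2 (-3.96 ± 0.44) lay below that sum. Mean Ptx3 was 0.838 CPM with vehicle (n = 3) and 35.1 and 27.0 CPM with BO-112 and DMXAA (n = 4 each), and it was 4.71 ± 0.51 above vehicle with both agents. For Ifnb1 the interaction was -3.33 ± 0.57 (adjusted p = 0.0135), for Ccl5 -2.95 ± 0.49 (adjusted p = 0.0119) and for Isg15 -2.24 ± 0.27 (adjusted p = 0.00214). The lipid transporter Abca9 (2.44 ± 0.46) and the pro-apoptotic gene Bmf (1.69) lay above the sum, but both calls ended without vehicle 1, without vehicle 3 and without the 4 libraries high in muscle genes.

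The interferon-stimulated list lay below the sum in 21 of 32, and in 29 adjusted over the list alone (camera adjusted p = 8.74e-37, adjusted p = 0.105 with an estimated correlation). Chemokines lay below it in 5 of 19, and in 10 adjusted over the list alone (camera adjusted p = 6.65e-09, adjusted p = 0.105 with an estimated correlation). Neutrophil markers lay below it in 4 of 20, and in 8 adjusted over the list alone (camera adjusted p = 1.88e-07, adjusted p = 0.273 with an estimated correlation). Yet the mean of that list was 2.95 log2 CPM with both agents, against 2.56 with BO-112 and 2.45 with DMXAA. With both agents S100a8 stood at 17.1 CPM, where the changes in CPM would add up to 15.2. Ifnb1 (1.71 against 7.45) and Isg15 (305 against 681) lay below such a sum. Cytotoxic genes lay below the sum of log2 changes in 3 of 18, and in 7 adjusted over the list alone (camera adjusted p = 4.75e-09, adjusted p = 0.199 with an estimated correlation). The 3 were Gzma (-2.03 ± 0.41), Prf1 (-1.76 ± 0.36) and Nkg7 (-1.36 ± 0.29). Monocyte markers lay below it in 3 of 16, and 5 below and 1 above adjusted over the list alone (camera adjusted p = 0.0146, adjusted p = 0.417 with an estimated correlation), a call that ended without DMXAA 1 (median -0.13).

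In total 239 genes departed from the sum, 35 above and 204 below. The count was 65 and 84 without vehicle 1 and vehicle 3, 116, 103, 127 and 139 without BO-112 1 to 4, 456 without DMXAA 2, 105 and 91 without replicates 3 and 4 of the tumours with both agents, 114 with scaling by total count alone (38.6% above, against 14.6% here), 645 with array quality weights and 36 without the 4 libraries high in muscle genes, which also ended the calls of Ifnb1, Ccl5, Slpi, Gzma, Prf1 and Nkg7. The share above the sum was 1.54% without vehicle 1, 2.38% without vehicle 3 and 0% without those 4 libraries. Of 44 named calls, 20 held with each library left out and 24 did not. Genes past both single agents in the same direction numbered 0 by limma and 0 by limma-voom, with 1690 and 4239 genes at an unadjusted p below 0.05 in the 2 comparisons behind that count. Both fits called 0 genes for both agents against BO-112, so this count could only be 0 and adds no result of its own.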

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

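Of the tests in this part, the correlation with transcript length and the second muscle list were set down before their results were seen, and the other tests of explanations were chosen after. In each group of 4 tumours the highest and lowest library were compared with the other 3; chance alone picks out about 1 in 20 groups, which is 8.55 of the 171 groups examined. The 6 values that stood apart are fewer than that, so their number gives no reason to look beyond chance. The values examined overlap in genes and libraries, so the count cannot decide about any 1 of them. The muscle value of BO-112 1 was also examined with a second gene list, given below.

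DMXAA 2 had a median correlation of 0.933 with its own group, against 0.966 to 0.968 for the other 3 DMXAA tumours, and a first component value of -131.91, against -60.35 for DMXAA 3, the next lowest of the 15 libraries. A loss of reads from long transcripts may contribute, as its difference from the other DMXAA libraries ran with transcript length at a Spearman correlation of -0.477 over 13451 genes, the lowest of the 15 libraries against their own groups (genes are not independent replicates). Against all other libraries DMXAA 3 was as low (-0.509, with -0.504 in DMXAA 2), and transcript length as the whole cause is argued against by a first component value of -126.84 with the length trend removed. Low depth is argued against by 5 libraries with fewer reads and at most 202 genes at 0 reads against its 622. Fat taken with the tumour is argued against by DMXAA 1 of the same group. Its adipocyte mean was near (3.40 against 3.85) and its first component value was 1.12. BO-112 2 was nearer in fat (3.69) with a value of 47.14, but all BO-112 tumours lay at 38.46 to 47.14. What else set this tumour apart stays open, and no biological explanation was tested. DMXAA 3 shared part of the pattern, with short and long transcripts at 0.34 and -0.31. Mitochondrial genes took 0.81% of the reads in DMXAA 2 and 0.96% in DMXAA 3, against at least 1.37% in the other libraries. Both are DMXAA tumours, so a cause tied to the treatment cannot be told apart from one tied to these tumours.

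The second pattern is that type I interferon-stimulated genes were lower with both agents than with BO-112 alone, by a median of -0.70 (adjusted p = 0.148 with an estimated correlation), while the interaction test found 239 genes and 20 gene lists whose DMXAA effect differed with and without BO-112 (0 lists with an estimated correlation, and as many as 20 in 14 of 100 splits of the samples). The scaling of the libraries is argued against by a median of -0.61 under the scaling that brought it nearest to 0. The macrophage list had a median of 0.0866, with 16 of its 22 members above 0. BO-112 itself lowered the mean of that list, to 6.38 from 6.90 log2 CPM with vehicle. A weaker response to BO-112 could thus raise the list whatever the number of macrophages, and fewer macrophages stays open. An even loss of the whole BO-112 response stays open: against the BO-112 response, the level with both agents was 70.5% ± 9.85 (SD, n = 4) in the interferon list, 79.4% ± 8.70 in the inflammatory list and 115% ± 28.1 in the neutrophil list, above the interferon list in 4 of 4 tumours for each of the other 2. DMXAA alone gave 34.9%, 41.1% and 95.7% of the BO-112 response in these lists, so the shares do not measure what was kept. Whether DMXAA lowered the interferon response to BO-112 was not tested apart from this difference, and an earlier peak or another change in cell content also stays open.

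Skeletal muscle genes were high in BO-112 1, with a list mean of 4.77 log2 CPM against -2.35 to -1.49 in the other BO-112 tumours, and also in vehicle 2 (3.26), DMXAA 1 (5.42) and DMXAA 3 (4.48). Skeletal muscle taken with the tumour is a candidate source: a second list of 16 muscle genes, none of them on the first list, was higher in 4 of these 4 libraries (1.80 to 3.44) than in any of the other 11 (at most -0.35), and Acta1 stood at 58.0 to 291 CPM against at most 5.60 CPM elsewhere. The treatment as the cause is argued against because the 3 groups concerned also hold tumours without these genes. Whole tumours were sequenced, with no sort or gate in the labels that would remove muscle.

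Other libraries apart from their group were BO-112 2 in the interferon list (8.62 against 8.35 to 8.38), replicate 1 of the tumours with both agents in epithelial genes (-1.46 against -0.07 to 0.20), and replicate 3 of the same group in the hypoxia list (6.68 against 6.82 to 6.85). In replicate 1 of the tumours with both agents, the 10 most abundant genes took 5.08% of the reads, against 4.66% to 4.70% in the other 3.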

How the results depend on the processing

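Chosen after the data were seen were array quality weights, removal of the length trend, leaving out the 4 libraries high in muscle genes and leaving out libraries of a group not compared. The other alternatives were planned, except limma-voom for the gene lists. Not run were the planned edgeR and DESeq2 tests and the version with no filter. Depth limits genes near or below 1 CPM, such as Ifnb1 in vehicle tumours (0.139 CPM). With scaling to a geometric mean, the stricter filter and the replicate block, each gene count lay within 1.5 times its value. The block gave 1762, 283 and 471 genes for BO-112, DMXAA and both agents against vehicle. It gave 0 for both against BO-112, 168 for both against DMXAA and 3828 for BO-112 against DMXAA. For the interaction it gave 283 and for the overlap 202. The replicate number need not mark a pairing, so the block cannot show that no batch exists.

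In that order of comparisons, a fit to the 2 groups alone gave 4320, 4, 748, 362, 4 and 1262 genes, and 4 for the overlap. Array quality weights gave 5006, 351, 1403 and 313 in the first 4, 645 for the interaction and 289 for the overlap. Without the 4 libraries high in muscle genes there were 1090 for BO-112, 24 for DMXAA, 1 for both against DMXAA, 791 for BO-112 against DMXAA, 36 for the interaction and 23 for the overlap. Removing the length trend gave 147 for DMXAA, 6 for both against BO-112, 272 for both against DMXAA and 107 for the overlap. Scaling by total count alone gave 105 for DMXAA, 3 for both against BO-112, 114 for the interaction and 85 for the overlap, and moved the median of all genes in BO-112 against vehicle from -0.04 to -0.20. Limma-voom gave 93 for DMXAA and 70 for the overlap, and an adjusted p of 0.01 left an overlap of 37. Some of these fits use fewer libraries or a stricter threshold, which does not account for counts that rose. In the main fit all 4 groups share an estimate of the spread between tumours. Leaving out DMXAA 2 alone gave 3524 for BO-112 and 32 for both against BO-112, though it is in neither comparison. The median changes of all genes stayed at -0.0393 and 0.0135. The shared spread thus enters these counts, including the 0 for both against BO-112. In the fit to the 2 groups alone, the counts fell where the DMXAA group was compared (221 to 4, 157 to 4 and 3783 to 1262). Where it was not, they rose (2116 to 4320, 473 to 748 and 0 to 362). Array quality weights were lowest for DMXAA 2 and DMXAA 3 (0.085 and 0.346). The SE and adjusted p printed for comparisons with the DMXAA group may thus be too small. Beyond that the causes were not tested. With an estimated correlation, the list calls went from 19 to 3 for BO-112 and from 21 to 4 for both agents against vehicle, and to 0 in the other 5 comparisons, since that setting widens the test of each list.

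Leaving out each library in turn gave 1269 to 3524 genes for BO-112, 25 to 376 for DMXAA, 246 to 768 for both agents, 0 to 32 for both against BO-112, 0 to 1765 for both against DMXAA, 1879 to 5898 for BO-112 against DMXAA, 65 to 456 for the interaction, 21 to 237 for the overlap and 0 to 0 for genes past both single agents. Genes past both single agents can only be 0 in a fit with 0 calls for both against BO-112. Counts moved over 1.5 times with 3, 3, 5, 2, 11 and 6 of the 15 libraries left out in the 6 comparisons, 9 in the interaction and 2 in the overlap. List calls ranged from 17 to 22, 10 (without DMXAA 1) to 20, 19 to 23, 15 to 20, 12 to 16, 14 to 19 and, for the interaction, 16 to 24. The lowest counts for DMXAA, the interaction and the overlap came without vehicle 1, those for BO-112 and both agents without vehicle 3, that for BO-112 against DMXAA without DMXAA 3, and those of 0 against DMXAA without replicate 1 or 2 of the tumours with both agents. The highest came without DMXAA 2 for BO-112, both agents, both against BO-112, the interaction and the overlap, without DMXAA 4 for DMXAA, and without DMXAA 1 for both comparisons against DMXAA.

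Lists that turned direction were interferon-gamma response for DMXAA (-0.38 without vehicle 3, adjusted p = 0.00174, and up to 0.68 without vehicle 2), skeletal muscle for both against BO-112 (0.16 without the 4 libraries or without BO-112 1, and down to -2.54 without BO-112 3) and in the interaction (1.19 without the 4 libraries), and oxidative phosphorylation in the interaction (0.0364 with array quality weights). Their cause was not tested, except that the muscle libraries are those left out. Of 231 list results, 223 kept direction and side of the threshold with the replicate block, 227 with limma-voom, 220 with total count alone and 115 with an estimated correlation, which ended 116 calls.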

Other observations

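Of the tests in this part, the permutation test on list means was chosen after the results were seen. Hypoxia response genes were higher with BO-112 than with vehicle in 15 of 24 and lower in 1, and 20 and 1 passed adjusted over the list alone (camera adjusted p = 3.79e-10, adjusted p = 0.139 with an estimated correlation). The mitophagy receptor Bnip3 rose by 1.38 ± 0.19 (SE) and the angiogenic factor Vegfa by 0.81 ± 0.18, while the glycolytic regulator Pfkfb4 fell by 0.91. With DMXAA 0 of 24 passed over all genes and 1 was higher adjusted over the list alone (camera adjusted p = 0.647), and Vegfa was higher with BO-112 than with DMXAA by 1.16 ± 0.17. Complement and coagulation genes were higher with BO-112 in 13 of 20 and lower in 1 under both adjustments, the second adjusted over the list alone (camera adjusted p = 1.13e-09, adjusted p = 0.0924 with an estimated correlation). The complement component C2 rose by 2.36 and the protein C receptor Procr by 1.79. Immediate early and heat shock genes were higher in 6 of 18, and in 10 adjusted over the list alone (camera adjusted p = 2.07e-06, adjusted p = 0.139 with an estimated correlation). The phosphatase Dusp1 rose by 2.81. Checkpoint and costimulation genes were higher in 9 of 22 and lower in 1, and 10 and 2 passed adjusted over the list alone (camera adjusted p = 1.67e-06, adjusted p = 0.259 with an estimated correlation). Cd274 rose by 2.34 ± 0.38, Cd40 by 2.50 and Lgals9 by 1.37, and the median of the immune checkpoints was 0.94, or 0.59 without vehicle 3. Cell death genes were higher in 11 of 25, and in 15 adjusted over the list alone (camera adjusted p = 5.73e-09, adjusted p = 0.0306 with an estimated correlation). Mlkl, the executor of necroptosis, rose by 1.11. Cholesterol synthesis genes were lower in 8 of 22, and in 11 adjusted over the list alone, with Dhcr7 at -0.81 ± 0.12 (camera adjusted p = 2.27e-08, adjusted p = 0.259 with an estimated correlation).

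Among cell type lists with BO-112, endothelial markers had 2 of 25 higher and 1 lower under both adjustments, the second adjusted over the list alone (camera adjusted p = 0.0317, adjusted p = 0.677 with an estimated correlation). That call ended without vehicle 3 or BO-112 2. The VEGF receptor Kdr rose by 2.05 ± 0.29, while Pecam1 was at 0.02 ± 0.18 (adjusted p = 0.966). Monocyte markers had 5 of 16 higher, among them Ly6c2 (3.54 ± 0.32), and 2 lower, among them the fractalkine receptor Cx3cr1 (-2.27), and 6 and 4 adjusted over the list alone (camera adjusted p = 0.0806). B cell markers had 2 of 12 higher, among them the B cell factor Pax5 (3.88 ± 0.51), and 1 lower under both adjustments, the second adjusted over the list alone (camera adjusted p = 0.462). NK cell markers had 1 of 18 higher and 2 lower, and 2 and 2 adjusted over the list alone (camera adjusted p = 0.934). Fibroblast and matrix genes had 2 of 22 higher under both adjustments, the second adjusted over the list alone, among them Dcn (1.06), whose call ended without the 4 libraries high in muscle genes (camera adjusted p = 0.234). Epithelial genes had 1 of 5 higher and 2 lower, and 2 and 2 adjusted over the list alone (camera adjusted p = 0.462). Skin, pericyte, erythroid and adipocyte lists had 0 members past the threshold under either adjustment, with camera adjusted p-values of 0.137, 0.72, 0.234 and 0.983. Regulatory T cell markers had 1 of 11 higher, Il10 (1.54), whose call ended without vehicle 3 or BO-112 2, and 2 adjusted over the list alone (camera adjusted p = 0.0457, adjusted p = 0.607 with an estimated correlation); the list call ended without vehicle 3, BO-112 2, BO-112 4 or DMXAA 2. Mast cell, basophil and eosinophil markers had 1 of 12 higher, the histamine enzyme Hdc (3.02), which the neutrophil list also holds, under both adjustments, the second adjusted over the list alone (camera adjusted p = 0.373). The list of interferon genes had 2 measured members, 1 of them higher, and was not tested as a list.

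Other splits of the same libraries were counted for each comparison. The real split gave the largest count of 35 for BO-112 (2116, highest of the other splits 2) and for both agents (473 against 100). It did so too for both agents against DMXAA (157 against 74) and between the single agents (3783 against 1). The other splits mix tumours of the 2 groups, so an effect of the agents widens their spread and lowers their counts. The gaps are thus partly built in, and a share of 1 in 35 is not adjusted over the 6 comparisons. The count of 157 also fell to 0 without replicate 1 or 2 of the tumours with both agents. Chance cannot be excluded for the genes changed with DMXAA (221 against 3899). For both agents against BO-112 and for genes past both single agents the splits decide nothing, since a count of 0 by limma is met by 35 of 35 and 100 of 100 splits whatever they give (highest of the others 0 and 0). The split with 3899 genes sets vehicle 3, DMXAA 2 and DMXAA 3 against the other 4 libraries, which points to a structure of the samples other than the treatment. For the interaction (239) and the overlap (165) the splits do not settle whether chance is enough, because they mix tumours with and without BO-112 and its effect then widens the spread and lowers the other counts. In each, 2 of 100 splits were as large, the real one included, and the highest others, 803 and 2786, also put vehicle 3, DMXAA 2 and DMXAA 3 together, which points to the same structure. For the number of list calls chance cannot be excluded in any of the 7 comparisons, with 19 against 24, 17 against 20, 21 against 26, 17 against 26, 12 against 20, 17 against 21 and, for the interaction, 20 against 23. As many were called by 20, 7, 11, 18, 20 and 6 of 35 splits in the 6 comparisons and by 14 of 100 in the interaction. Means of whole lists compared by exact permutation gave an adjusted p of at least 0.0555 in each comparison, with 0.0286 the smallest p the test can give before adjustment. That smallest p was reached by 17, 7, 10, 4, 3 and 9 of 33 lists in the 6 comparisons. An adjusted p below 0.05 needs many lists at that smallest p, so this test could hardly pass a list and decides little. The lists are not independent.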
